A study of Drosophila melanogaster with 12 samples.

How the data were processed

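RNA from adult heads of y w; tim01 flies was hybridised to 12 arrays, 1 for each time point, and nothing was averaged between arrays. Per the labels, about 100 to 200 heads were taken per sample, RNA was total RNA, and about 25 µg of it was made into biotin-labelled cRNA. The deposited table holds log2 values, 1 per probe set and array, which the authors made with RMA (background correction, normalization between arrays and summary of the probes of a probe set), per the submitters' processing notes; the version, the software and the probe definition are not given in the sources used here. The log2 scale was also seen in the values, which ran from 1.52 to 13.74, and the array medians lay between 4.10 and 4.14 with interquartile ranges from 2.31 to 2.38. RMA brings the arrays to nearly one distribution, so a change of the total RNA or of most transcripts at once cannot be seen, and it compresses changes of dim probe sets. The files give no counts or detection calls; the number of arrays limits the precision.

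Arrays were grouped by the hour in their titles: LD light phase (ZT2, ZT6 and ZT10), LD dark phase (ZT14, ZT18 and ZT22), DD subjective day (CT2, CT6 and CT10) and DD subjective night (CT14, CT18 and CT22), 3 arrays each. The arrays of a group are different time points, and no label says that any time point was sampled more than once. The spread behind the group SDs and the SEs and p of the group contrasts is therefore that between the hours of a phase, technical differences included. For the rhythms it is the scatter of the arrays around the fitted curves. The LD and DD arrays share their clock hours, and clock hour as a block was run as an alternative; no label says that arrays of the same hour share flies or a batch. The most alike pair of arrays shared 55 identical values of the 14010 probe sets, so no array was a copy of another.

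Of 14010 probe sets, 44 control probe sets were left out and 13966 were tested. The platform annotation gave 1 gene symbol to 12443 probe sets, several to 327 and none to 1196; 12394 of the probe sets with 1 gene were matched through their Entrez number to the RefSeq gene table, and 0 symbols had to be changed. Probe sets with several symbols or none were counted but not named. No genome was used, so no positions are given.

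The tests were run with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with the intensity trend) on the log2 values of all 12 arrays, with Benjamini-Hochberg adjustment over the 13966 probe sets and a threshold of 0.05 on the adjusted p. A model with 1 mean per group (8 residual degrees of freedom, prior degrees of freedom 8.62) gave 6 contrasts: light against dark phase in LD, subjective day against subjective night in DD, the difference of these contrasts, LD light phase against DD subjective day, LD dark phase against DD subjective night, and the DD day against the LD day. A model with a mean, a cosine and a sine of a 24 h cycle per day (6 residual degrees of freedom, prior degrees of freedom 8.41) gave moderated F tests of the rhythm in LD, of that in DD and of their difference. Amplitudes are fitted values on the log2 scale (mean to peak), and peak times come from the fitted curve. SEs are limma's, from the moderated variance. SDs are over the 3 arrays of a group, or over the 6 arrays of a day where this is stated.

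For lists of genes fixed before the data were examined, each gene was represented by its probe set with the highest mean over the 12 arrays (10844 distinct genes). Shifts of 30 lists were tested with limma's camera with a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with the correlation estimated from the data. The lists cover the core clock, reported clock outputs in heads, phototransduction, retinoid and eye pigment metabolism, activity-regulated genes, histamine, dopamine and serotonin handling, heat shock, immune effectors, cytochrome P450, glutathione S-transferases, UDP-glycosyltransferases, antioxidant enzymes, glycolysis, lipid metabolism, starvation and insulin signalling, ecdysone and juvenile hormone, neuropeptides, odorant-binding proteins, cuticle proteins, ribosomal proteins, oxidative phosphorylation, proteasome, and markers of neurons, glia, fat body, muscle, gut, male reproductive tract, eggshell and hemocytes. Counts adjusted over the list alone use the members' unadjusted p.

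Genes were named by a rule fixed before the data were examined: tim first on every array; among probe sets with 1 symbol that passed, the 12 with the largest change in each direction (for the comparison of days 6, for rhythms the 24 with the largest amplitude); where fewer than 5 passed, the 5 with the smallest p, given as not passing; all measured core clock genes; and up to 4 members of each other list with the smallest p. Where a named gene has several probe sets that disagree, this is stated.

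The steps were tested on simulated data with the moderated spread of these arrays and 200 of 13966 probe sets changed. The noise was drawn independently for each probe set and array, so genes were not correlated and no array stood apart. The rates below hold for such data and may not carry over to the real arrays. In the contrast of light and dark phase in LD, 96 of 100 probe sets changed by 0.5 and 100 of 100 changed by 1 were found, with 12 false calls. In the DD contrast 95 and 99 of 100 were found with 13 false calls, in that of LD light phase and DD subjective day 96 and 100 with 11 false calls, and in that of the days 99 and 99 with 9 false calls. LD rhythms of amplitude 0.4 and 0.8 were found in 100 and 100 of 100 cases with 11 false calls, and DD rhythms in 93 and 100 with 13 false calls. In the LD contrast, 1 list of 16 genes shifted by 0.3 was found and 0 of the other lists were called, over 10844 genes.

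Alternatives fixed before the data were examined were: probe sets above the median signal only, quantile normalization again, centring each array on its median, no intensity trend, robust moderation, array weights, a linear slope in hours within each day, the compared arrays alone, clock hour as a block, camera with an estimated correlation, all probe sets of a gene in the list tests, and leaving out each array in turn. Leaving out the ZT2, ZT18 and CT2 arrays, a covariate of gut and male reproductive tract transcripts, and a covariate of the 3' minus 5' signal of the eIF-4a control transcript, were chosen after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.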

Results

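Transcript levels in heads of y w; tim01 flies, which carry a loss-of-function allele of the clock gene timeless, were measured over 2 successive days. The flies had been kept for 3 days in cycles of 12 h of light and 12 h of darkness. Heads were then sampled every 4 h through 1 more light-dark day (LD, ZT hours counted from lights-on) and through the next day in constant darkness (DD, CT hours counted from the time at which lights would have come on). Of the 12 arrays, 3 fell into the LD light phase (ZT2, ZT6, ZT10), 3 into the LD dark phase (ZT14, ZT18, ZT22), 3 into the DD subjective day (CT2, CT6, CT10) and 3 into the DD subjective night (CT14, CT18, CT22). Values are log2 RMA signals, with array medians from 4.10 to 4.14 and correlations between arrays, across probe sets, from 0.988 to 0.997. Each array is another time point, so errors and p-values of the group contrasts measure the spread between the hours of a phase. Those of the rhythms measure the scatter of the arrays around the fitted curves. Wild-type flies were not analysed here.

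Transcripts that belong to other parts of the body stood high on 3 of the 12 arrays. The mean level of 22 gut enzyme genes, relative to each gene's mean over all arrays, was 0.77 at ZT2, 0.06 at ZT18 and 0.45 at CT2, against -0.20 to -0.04 on the other 9 arrays. The level of 17 genes of the male reproductive tract was 0.75, 0.30 and 0.45 on the same arrays, against -0.25 to -0.03. The digestive protease gene betaTry read 8.66, 7.07 and 7.92 there and 6.12 to 6.31 elsewhere, and Mst57Da, expressed in male accessory glands, read 7.26, 6.01 and 6.50 against 3.83 to 4.29. The 12 eggshell genes did not stand apart, at -0.03, 0.00 and -0.03 against -0.05 to 0.11. The 3 arrays lie in the LD light phase, the LD dark phase and the DD subjective day, and counts without them are given beside each comparison.

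**Figure D1:**
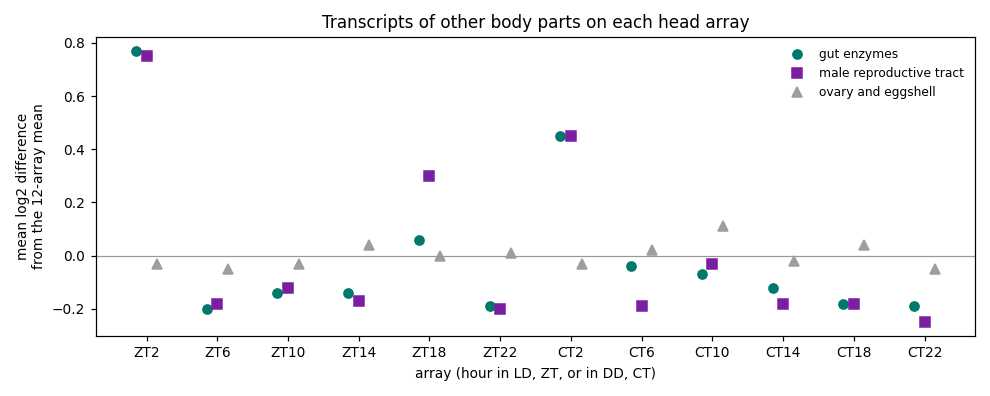
Mean level of the gut enzyme, male reproductive tract and eggshell lists on each of the 12 arrays (log2, relative to each gene's mean over the arrays) with arrays in order of hour on the LD day and then the DD day and 1 colour and symbol per list. The gut list reaches 0.77 at ZT2 and 0.45 at CT2, while the eggshell list stays between -0.05 and 0.11.

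The gene tim itself, measured by its brightest probe set, gave a steady signal in all samples. It read 7.12, 7.05, 6.93, 6.92, 6.87 and 6.97 from ZT2 to ZT22 and 6.78, 6.92, 6.62, 6.90, 6.74 and 6.65 from CT2 to CT22. The mean was 6.98 ± 0.09 in LD and 6.77 ± 0.13 in DD (SD, n = 6 arrays each), a change of -0.21 ± 0.06 (SE) that did not pass (limma, adjusted p = 0.209). Where this probe set lies relative to the lesion is not known here, so its signal checks nothing about the genotype. The other tim probe sets read 1.82 and 3.92 on average.

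None of the 13 measured core clock genes passed in any of the 9 comparisons with limma, over all probe sets or adjusted over the list alone (0 in each). The transcript of per, the partner of tim in the feedback loop, lay between 4.66 and 4.92 on the 12 arrays. Levels of Clk and cyc, which encode the activators of that loop, ran from 2.72 to 3.18 and from 5.30 to 5.78. Those of vri and Pdp1, transcription factor genes driven by the activators in wild-type flies, ran from 7.97 to 8.29 and from 6.33 to 6.58. The photoreceptor gene cry lay between 6.43 and 6.81, the repressor gene cwo between 5.01 and 5.53, and the neuropeptide gene Pdf between 6.33 and 6.70. The median fitted 24 h amplitude of the list was 0.11 in LD and 0.09 in DD. The probe sets of Clk and slmb (group means of slmb from 2.78 to 3.05) were dim, below the array medians of 4.10 to 4.14. RMA compresses changes of dim probe sets, so their narrow ranges may understate a change.

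**Figure D2:**
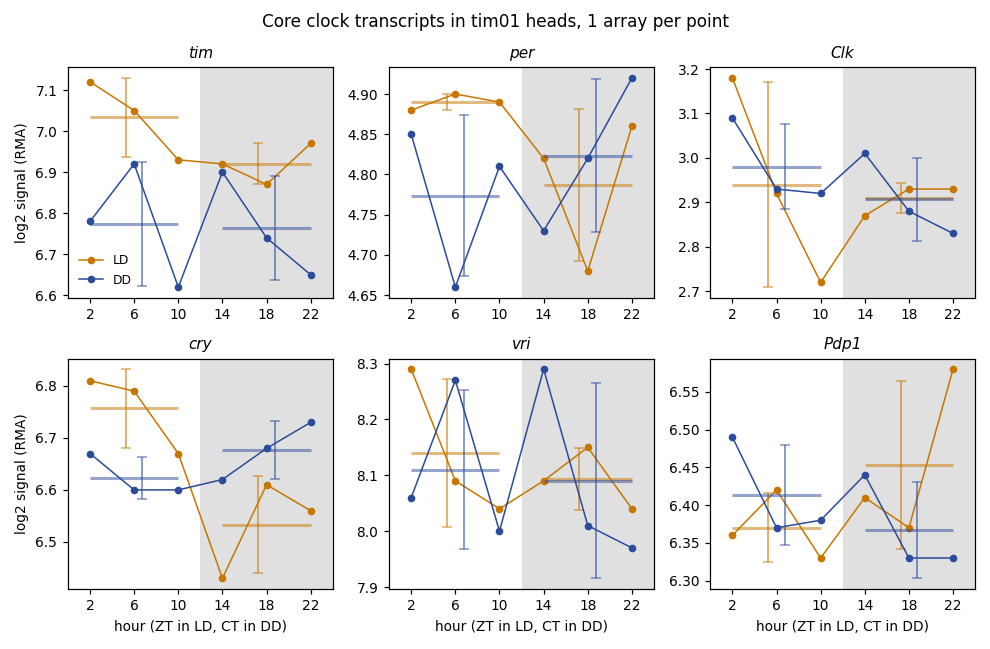
Log2 signal of core clock genes against hour on the LD day and the DD day, 1 point per array, with group means of 3 arrays as thick lines, SD as bars and grey shading for darkness or subjective night. The signal of per stays between 4.66 and 4.92 and that of vri between 7.97 and 8.29.

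The contrast of light and dark phase in LD asks which transcripts follow the light-dark cycle in flies without a working timeless gene. In the light phase, CG5455 was 1.81-fold higher (log2 change 0.86 ± 0.10 SE, adjusted p = 0.0026), at 7.03 ± 0.11 against 6.18 ± 0.07 in the dark phase (SD, n = 3 arrays each), and the carbonic anhydrase gene CAH5 1.64-fold (0.72 ± 0.09, adjusted p = 0.0026). The means of CAH5 were 7.40 and 6.68 in LD, and 7.35 and 6.90 in the subjective day and night of DD. Its LD contrast therefore does not by itself show a response to light. For CG5455 the DD means were 6.05 and 6.11. Also higher were Usp8, a ubiquitin-specific protease gene (0.90 ± 0.16), CG4757 (0.86 ± 0.14), Lsd-1, which encodes a lipid droplet protein (0.54 ± 0.10), and NAT1 (0.51 ± 0.08). The largest fall was that of retinin, a protein gene of the corneal lens, by 0.72 on the log2 scale (SE 0.11, adjusted p = 0.0158). Other transcripts lower in the light were those of M7BP (-0.66 ± 0.12), CG6429 (-0.64 ± 0.12), CG8468 (-0.63 ± 0.10), the antibacterial peptide gene Def (-0.62 ± 0.12), CG8157 (-0.59 ± 0.10), Drat (-0.53 ± 0.10), Epac, a cAMP-regulated exchange factor gene (-0.49 ± 0.08), and the retinol dehydrogenase gene rdhB (-0.45 ± 0.08), with adjusted p from 0.03 to 0.0459.

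In all, 18 probe sets passed (9 higher and 9 lower in the light), 15 of them with 1 gene symbol, and 874 had an unadjusted p under 0.05 where chance gives 698. Other probe sets of M7BP, CG8468 and Epac showed smaller changes that did not pass (-0.11 to 0.02, -0.13 and -0.04). The count was 0 with a linear slope in hours, 1 from the 6 LD arrays alone, 2 without ZT6, 3 with the eIF-4a measure of RNA quality given below as a covariate and 54 without ZT2. Without the ZT2, ZT18 and CT2 arrays it was 31 (26 higher and 5 lower), with 9 of the 18 among them.

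**Figure D3:**
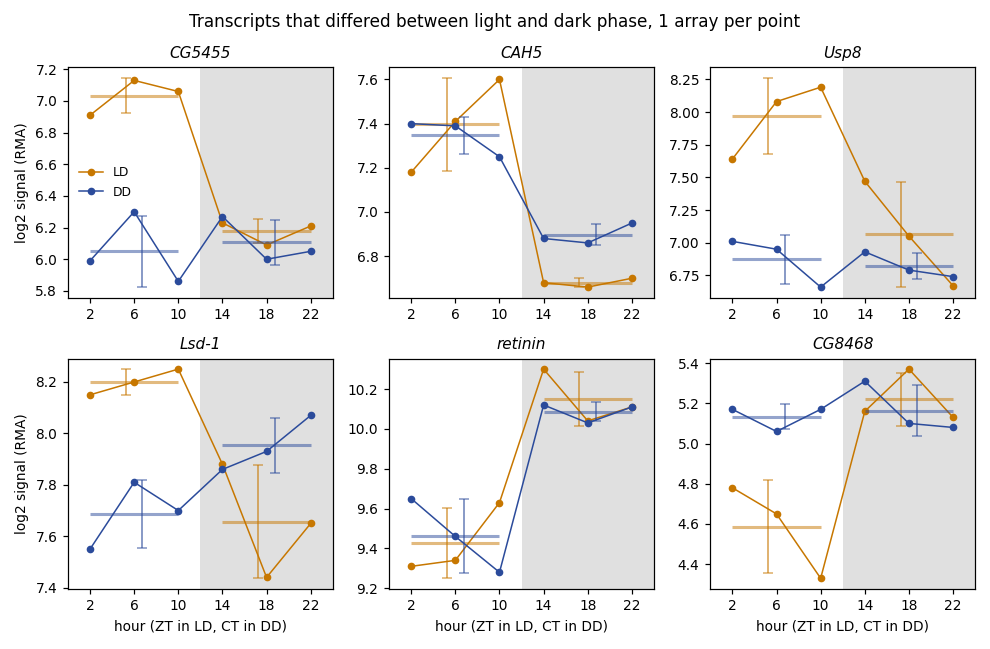
Log2 signal against hour of genes called between light and dark phase in LD, 1 point per array for the LD day and the DD day, with thick lines for group means of 3 arrays, bars for SD and grey shading for darkness or subjective night. CG5455 lies at 7.03 on average in the light phase and at 6.18, 6.05 and 6.11 in the other 3 groups.

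Of the 30 gene lists, 12 shifted between light and dark phase with camera at a preset correlation of 0.01, and 0 passed with an estimated correlation. Among 9 immune effectors, 1 fell (Def) and 0 rose over all probe sets, while 4 higher and 1 lower were counted adjusted over the list alone. The antimicrobial peptide genes Mtk (1.05 ± 0.28), DptB (0.92 ± 0.20) and Drs (0.76 ± 0.16) had the largest positive changes, and the list's mean was 0.29 (adjusted p = 0.00833, and adjusted p = 0.438 with an estimated correlation). The 19 phototransduction genes had a mean of 0.09, 14 of them positive (adjusted p = 0.0139, and adjusted p = 0.323 with an estimated correlation). None of these passed over all probe sets with limma, and 3 higher and 1 lower did adjusted over the list alone: the photoreceptor channel gene trpl (0.66), the scaffold gene inaD (0.39), the protein kinase gene inaC (0.36) and the rhodopsin phosphatase gene rdgC (-0.43). In lipid metabolism, 13 of 16 genes were positive with a mean of 0.13 (adjusted p = 0.00197, and adjusted p = 0.187 with an estimated correlation), and 1, Lsd-1, passed both over all probe sets and adjusted over the list alone. The 9 activity-regulated genes and the 6 heat shock genes each had a mean of 0.13 (adjusted p = 0.00833 and 0.00712, and adjusted p = 0.187 for each with an estimated correlation), with 1 member of each adjusted over the list alone, sr at 0.41 and DnaJ-1 at 0.26, and 0 over all.

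Lists lower in the light were those of eye pigments, fat body, odorant-binding proteins, cuticle and respiration. Of 13 genes of retinoid and eye pigment metabolism 11 were negative, with a mean of -0.09 (adjusted p = 0.00833, and adjusted p = 0.187 with an estimated correlation). None passed over all probe sets (0 of 13) and 3 did adjusted over the list alone, Pdh (-0.31), pr (-0.30) and st (-0.30). The 9 fat body markers had a mean of -0.22 (adjusted p = 0.00276, and adjusted p = 0.323 with an estimated correlation), with Obp99a at -0.79 and fit at -0.49 adjusted over the list alone and 0 over all. This shift rested mostly on ZT10 and ZT14, where the list level was -0.30 and 0.31, against -0.01 to 0.03 on the other LD arrays. Of 35 odorant-binding protein genes 25 were negative (mean -0.06, adjusted p = 0.0467, and adjusted p = 0.355 with an estimated correlation), with 1, again Obp99a, adjusted over the list alone. Among 58 cuticle protein genes 40 were negative (mean -0.05, adjusted p = 0.0167), and among 60 genes of oxidative phosphorylation 49 were (mean -0.07, adjusted p = 0.00197). Both lists had adjusted p = 0.535 with an estimated correlation and 0 members passing either way. The gut enzyme list (mean 0.23, 20 of 22 positive, adjusted p = 0.00833, and adjusted p = 0.663 with an estimated correlation) and the male reproductive tract list (mean 0.17, adjusted p = 0.0168, and adjusted p = 0.699 with an estimated correlation) were higher in the light phase, which holds the ZT2 array. Without ZT2 the mean was -0.02 for oxidative phosphorylation (adjusted p = 0.444), -0.05 for eye pigments (adjusted p = 0.177), -0.03 for odorant-binding proteins (adjusted p = 0.463) and -0.04 for cuticle proteins (adjusted p = 0.0811). When ZT2, ZT18 and CT2 were left out, the gut list was at -0.01, the male list at 0.03 (adjusted p = 0.47) and the activity-regulated genes at 0.10 (adjusted p = 0.0515).

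In constant darkness, the contrast of subjective day and subjective night asks which transcripts differ by time of day without light. Among the named genes that passed, the antimicrobial peptide genes Mtk, DptB and Drs had the largest changes. The antifungal peptide gene Drs was 2.24-fold higher in the subjective day (log2 change 1.16 ± 0.16 SE, adjusted p = 0.00782), the antibacterial DptB 2.41-fold (1.27 ± 0.20, adjusted p = 0.0205) and Mtk 3.18-fold (1.67 ± 0.28, adjusted p = 0.0286). For Mtk the group means were 9.16 ± 0.44 and 7.49 ± 0.27 (SD, n = 3 arrays each), and for Drs they were 8.22 ± 0.25 and 7.06 ± 0.09. CG4757 was 2.02-fold higher (1.01 ± 0.14, adjusted p = 0.00782) and CG9150 higher by 0.54 ± 0.09 (adjusted p = 0.044). The corneal gene retinin fell by 0.62 (SE 0.11, adjusted p = 0.0333). Of the 9 probe sets that passed (8 higher, 1 lower, 816 with an unadjusted p under 0.05), 3 have no gene name, with changes of 1.51 ± 0.24, 1.40 ± 0.18 and 0.79 ± 0.11. The count was 0 with a linear slope in hours and without CT2 or CT22, 1 without CT18, 4 without CT14, 18 without ZT2 and 18 from the 6 DD arrays alone. Without the ZT2, ZT18 and CT2 arrays it was 12, all 9 included.

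Among the lists, 7 shifted between subjective day and night with the preset correlation and 0 with an estimated one. Immune effectors had the largest shift: 3 of 9 rose over all probe sets, 5 higher and 1 lower were counted adjusted over the list alone, and the mean was 0.55 (adjusted p = 2.26e-08, and adjusted p = 0.356 with an estimated correlation). The peptidoglycan recognition protein genes PGRP-SB1 (0.42) and PGRP-LB (0.24) and the antibacterial Def (-0.38) were the others adjusted over the list alone. The fat body markers, at -0.20, did not move with them (adjusted p = 0.013, and adjusted p = 0.748 with an estimated correlation), with 8 of 9 negative and 0 passing over all or adjusted over the list alone. The eye pigment list had a mean of -0.08 (adjusted p = 0.0499, and adjusted p = 0.579 with an estimated correlation), with pr at -0.27 adjusted over the list alone. Lipid metabolism was at -0.07 (adjusted p = 0.0272) and oxidative phosphorylation at -0.05 (adjusted p = 0.0185), each with 0 members passing over all or adjusted over the list alone and with adjusted p = 0.748 with an estimated correlation. The gut list (mean 0.28, adjusted p = 0.000199) and the male reproductive tract list (mean 0.28, adjusted p = 0.000969) were higher in the subjective day, which holds the CT2 array, each with adjusted p = 0.748 with an estimated correlation. Without CT2 the means were 0.11 (adjusted p = 0.254) and 0.09 (adjusted p = 0.406). The calls of eye pigments (-0.06, adjusted p = 0.254), lipid metabolism (-0.07, adjusted p = 0.0796) and oxidative phosphorylation (-0.03, adjusted p = 0.262) were then lost as well.

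**Figure D4:**
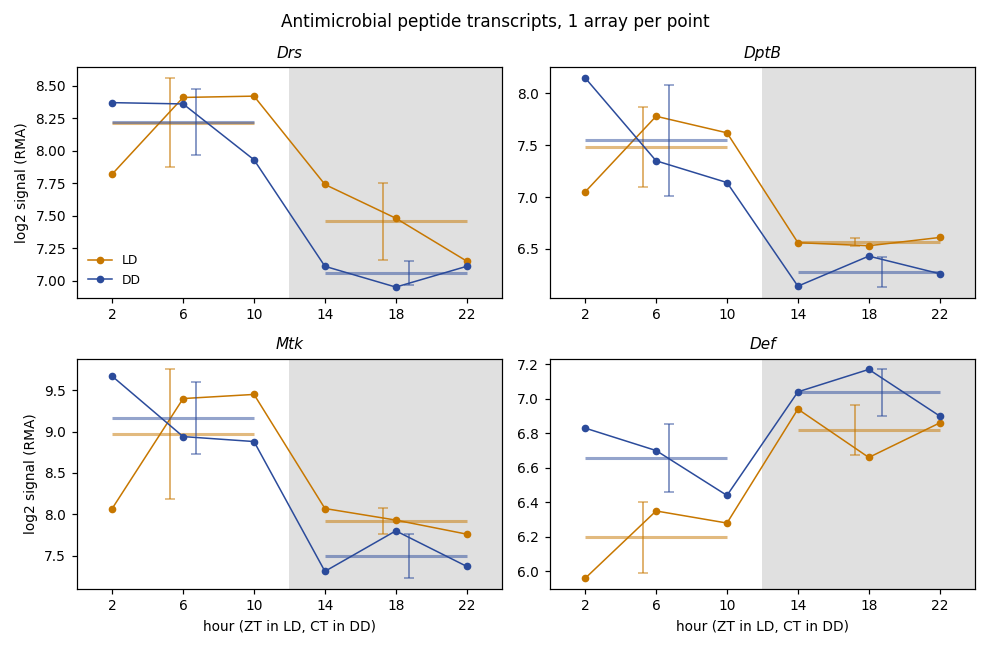
Log2 signal of antimicrobial peptide genes against hour on the LD day and the DD day, 1 point per array, with thick lines for group means of 3 arrays, bars for SD and grey shading for darkness or subjective night. In DD, Mtk lies at 9.16 on average in the subjective day and 7.49 in the subjective night, while Def lies at 6.66 and 7.04.

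Whether the day-night contrast differed between LD and DD was tested directly, and 0 probe sets passed with limma (727 with an unadjusted p under 0.05, smallest adjusted p 0.0898). The count was 3 with array weights, 3 with a covariate of gut and male reproductive tract transcripts, 2 with robust moderation and 4 with a covariate of RNA quality, the 3' minus 5' signal of eIF-4a. No fit with clock hour as a block was run for this difference. The nearest were CG5455, whose contrast was larger in LD by 0.91 ± 0.15, NAT1 (0.73 ± 0.12), Lsd-1 (0.81 ± 0.14, adjusted p = 0.121), M7BP (-0.93 ± 0.17, adjusted p = 0.124) and CR44101 (-0.56 ± 0.11, adjusted p = 0.279), none of them past the threshold. Lipid metabolism shifted as a list, with 13 of 16 genes positive and a mean of 0.20 (adjusted p = 6.82e-05, and adjusted p = 0.28 with an estimated correlation). Of its members 0 passed over all probe sets and 1, Lsd-1, adjusted over the list alone. The mean difference was 0.13 for activity-regulated genes (adjusted p = 0.0474, and adjusted p = 0.37 with an estimated correlation) and 0.12 for glycolysis (adjusted p = 0.0343, and adjusted p = 0.692 with an estimated correlation). All 9 immune effectors were negative, with a mean of -0.26 (adjusted p = 0.0193, and adjusted p = 0.772 with an estimated correlation), which became -0.02 without the ZT2, ZT18 and CT2 arrays. In that fit 0 probe sets passed, and activity-regulated genes (0.10, adjusted p = 0.168) and glycolysis (0.09, adjusted p = 0.184) lost their calls.

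The LD light phase and the DD subjective day cover the same clock hours with and without light. In the light, CG5455 was 1.98-fold higher (log2 change 0.98 ± 0.10 SE, adjusted p = 0.000564), at 7.03 ± 0.11 against 6.05 ± 0.23 (SD, n = 3 arrays each), and Usp8 2.14-fold (1.10 ± 0.16, adjusted p = 0.015). The actin nucleator gene spir was higher by 0.80 ± 0.13, c11.1 by 0.74 ± 0.14, CG2082 by 0.72 ± 0.10 and CG7220 by 0.58 ± 0.08. The co-chaperone genes Hsp110 (0.61 ± 0.11) and stv (0.57 ± 0.10) and the chaperonin subunit gene CCT2 (0.52 ± 0.10) also rose, while the heat shock list, with a mean of 0.10, did not pass (adjusted p = 0.137). Higher too were the fatty acid synthase gene FASN1 (0.66 ± 0.12), Pect, an enzyme gene of phosphatidylethanolamine synthesis (0.54 ± 0.09), and Lsd-1 (0.52 ± 0.10). The 5 that fell were Achl (-0.69 ± 0.12), Ttd14, a gene needed for trafficking of the TRPL channel (-0.59 ± 0.11), CG8468 (-0.55 ± 0.10), Drat (-0.55 ± 0.10) and CG9717 (-0.53 ± 0.09). In all, 26 probe sets passed (21 higher and 5 lower in the light), 25 of them with 1 symbol, and 1605 had an unadjusted p under 0.05.

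In this comparison, 6 of 16 lipid metabolism genes were higher adjusted over the list alone, ATPCL (0.37), AcCoAS (0.34), Desat1 (0.44) and Lpin (0.30) besides FASN1 and Lsd-1, which were the 2 that passed over all probe sets. The list's mean was 0.19 (adjusted p = 2.76e-05, and adjusted p = 0.231 with an estimated correlation). Activity-regulated genes had a mean of 0.14 (adjusted p = 0.0264, and adjusted p = 0.351 with an estimated correlation), with CG14186 (0.46), sr (0.35) and puc (0.25) adjusted over the list alone and 0 over all. Glycolysis had a mean of 0.11 (adjusted p = 0.0264, and adjusted p = 0.511 with an estimated correlation), with Gpdh1 (0.40) and Pgi (0.29) adjusted over the list alone and 0 over all. In 8 of the 10 splits of these 6 arrays, the real one included, at least as many lists shifted. The number of shifted lists therefore did not stand out from regrouped arrays. Glia markers went the same way without passing as a list, at 0.04, 0.14 and 0.04 from ZT2 to ZT10 and -0.09, 0.09 and -0.22 from CT2 to CT10. Neuron markers went the other way, at -0.12, 0.02 and -0.08 against -0.02, 0 and 0. Whether these levels are related to the shifts above was not tested. Other probe sets of spir (0.07 to 0.22), stv (0.05), CCT2 (0.14), CG8468 (-0.22) and Ttd14 (-0.33) had smaller changes that did not pass. A sign of RNA quality moved with this comparison: the signal of the eIF-4a control transcript at its 3' end minus that at its 5' end was 3.08 on average in the LD light phase and 2.70 in the DD subjective day, and 3.22 and 2.90 in the nights. With it as a covariate 0 of the 26 calls were kept (1 other passed), as the median SE grew from 0.10 to 0.14 while the median size went from 0.55 to 0.58. The list means were then 0.22 for lipid metabolism (adjusted p = 3.07e-05) and 0.13 for activity-regulated genes (adjusted p = 0.0847). The count was 0 from the 6 arrays alone, 1 without ZT6 or CT10, 4 without CT2, 56 without ZT2, 168 without CT6 and 142 with clock hour as a block. Without the ZT2, ZT18 and CT2 arrays it was 33, with 14 of the 26 among them.

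Between the nights of the days, both in darkness, 0 of 13966 probe sets passed with limma and 680 had an unadjusted p under 0.05, where chance gives 698. The genes with the smallest p were CG9150 (0.41), DCAF12 (0.38), Nplp3 (-0.39), EloB (-0.37) and eIF3d2 (-0.32, LD minus DD), each with adjusted p = 0.998. Of the 30 lists 0 shifted in the main fit. Some lists did pass without ZT2, ZT14 or ZT22, without the ZT2, ZT18 and CT2 arrays together, and with the eIF-4a covariate. When ZT2, ZT18 and CT2 were left out, 0 probe sets passed. The test of whether the days differ more by light phase than by dark phase is that of the day-night contrasts, in which 0 passed.

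Over the whole DD day against the whole LD day, 3 probe sets passed, all lower in DD. CG5455 fell by 0.53 (SE 0.07, adjusted p = 0.0236), CG2082 by 0.49 (SE 0.07, adjusted p = 0.0251) and spir by 0.58 (SE 0.09, adjusted p = 0.0432). CG11807 (-0.30 ± 0.05) and CG7220 (-0.35 ± 0.06) lay just above the threshold (adjusted p = 0.0503 each), and 1548 probe sets had an unadjusted p under 0.05. Lipid metabolism was lower in DD, with a mean of -0.09 (adjusted p = 0.0203, and adjusted p = 0.688 with an estimated correlation), 0 members over all, and FASN1 (-0.42), Desat1 (-0.37) and ATPCL (-0.21) adjusted over the list alone. The call of this list was lost without CT18 and with all probe sets of each gene. The DD day always followed the LD day, so light and day of sampling cannot be told apart here. The 3' minus 5' signal of eIF-4a also differed, at 3.15 ± 0.16 on the LD day and 2.80 ± 0.16 on the DD day (SD, n = 6 arrays each; exact permutation p = 0.00866 over 462 splits), as did that of GAPDH less clearly (2.45 ± 0.17 and 2.29 ± 0.10, exact p = 0.0649). With the eIF-4a measure as a covariate 0 probe sets passed, the median size of the 3 staying at 0.53 while the median SE grew from 0.07 to 0.13, and lipid metabolism was at -0.12 (adjusted p = 0.00898). With quantile normalization applied again the split was 3 higher and 15 lower in DD, against 0 and 3. The count was 0 without ZT6, ZT14, ZT18, CT10, CT18 or CT22, 95 without CT6, 26 without the ZT2, ZT18 and CT2 arrays, and 118 with clock hour, which the days share, as a block.

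A 24 h rhythm on the LD day passed for 15 probe sets, 13 of them with 1 symbol. The largest named amplitude was that of CG2121, 0.82 ± 0.06 on the log2 scale (SE; 3.11-fold from trough to peak, adjusted p = 0.000143), with values of 5.80, 6.64, 7.04, 6.53, 5.53 and 5.52 from ZT2 to ZT22 and a fitted peak at ZT 9.5. Of the other genes that peaked in the light, the photoreceptor channel gene trpl did so at ZT 7.4 (0.52 ± 0.08, 2.05-fold), the carcinine transporter gene CarT at ZT 9.3 (0.58 ± 0.09), the mitochondrial magnesium exporter gene MME1 at ZT 9.3 (0.58 ± 0.06), CG10126 at ZT 9.2 (0.58 ± 0.08), Drs at ZT 8.2 (0.64 ± 0.08), Usp8 at ZT 8.1 (0.73 ± 0.08), CAH5 at ZT 6.9 (0.50 ± 0.07) and CG5455 at ZT 6.3 (0.60 ± 0.08). The gene t (tan), whose enzyme regenerates the photoreceptor transmitter histamine, peaked at ZT 23.7 (0.62 ± 0.07, 2.35-fold, adjusted p = 0.00977). Peaks in the dark were also fitted for rdgC at ZT 21.1 (0.44 ± 0.06), Achl at ZT 20.1 (0.43 ± 0.06) and Drat at ZT 19.7 (0.41 ± 0.06), and the adjusted p of all 13 ran from 0.000143 to 0.0429.

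Phototransduction had 2 rhythmic members of 19 in LD over all probe sets, trpl and rdgC, and 6 adjusted over the list alone, with inaD (0.34), Gbeta76C (0.37), inaC (0.28) and Cds (0.23) added. Immune effectors had 1 of 9 over all (Drs) and 6 adjusted over the list alone, and reported clock outputs 1 of 10 over all (trpl) and 4 adjusted over the list alone, with Slob (0.45), Pdh (0.22) and Ugt35B1 (0.22) added. In lipid metabolism Lsd-1 (0.41) and SREBP (0.29) passed adjusted over the list alone and 0 over all. Second probe sets of CG2121 (amplitude 0.02) and CarT (0.28) did not pass. The count was 1 without ZT10, 6 from the LD arrays alone and 68 with a linear slope in hours. Without the ZT2, ZT18 and CT2 arrays it was 7, with 6 of the 15 among them, and trpl was then at 0.46 with adjusted p = 0.352.

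**Figure D5:**
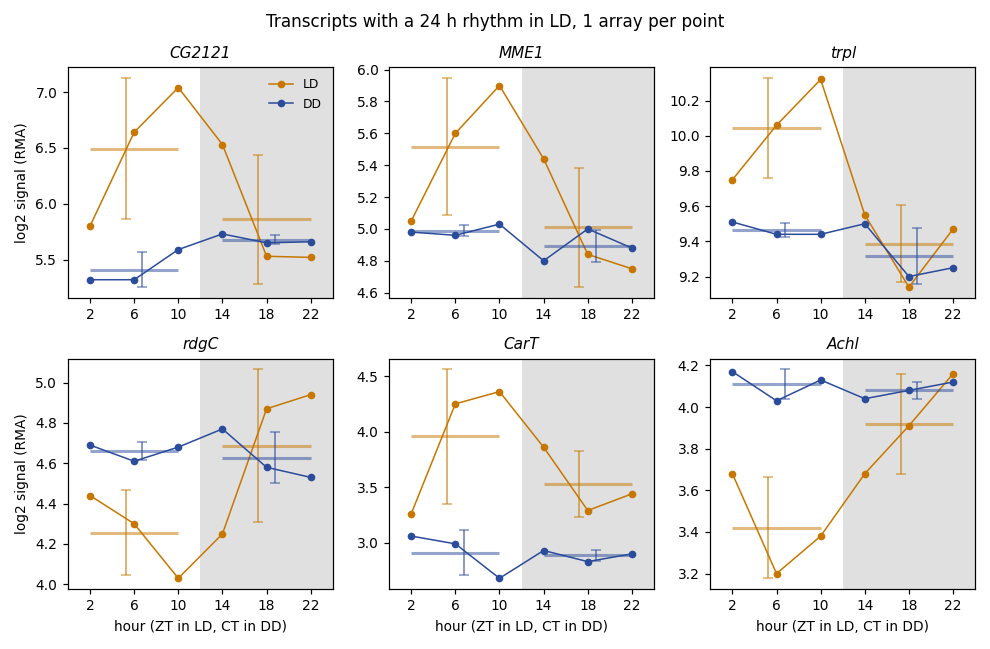
Log2 signal against hour of genes with a 24 h rhythm on the LD day, 1 point per array for the LD day and the DD day, with thick lines for group means of 3 arrays, bars for SD and grey shading for darkness or subjective night. CG2121 reaches 7.04 at ZT10 and lies between 5.32 and 5.73 on the DD day.

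On the DD day 1 probe set passed, that of Drs, with an amplitude of 0.83 ± 0.08 (SE; 3.14-fold from trough to peak, adjusted p = 0.00335) and a fitted peak at CT 5.4. In all, 519 probe sets had an unadjusted p under 0.05 in this F test, fewer than the 698 that chance gives. The values of Drs were 8.37, 8.36, 7.93, 7.11, 6.95 and 7.11 from CT2 to CT22. The next genes did not pass: CG4757 (0.69, adjusted p = 0.387), CG9150 (0.38, adjusted p = 0.387), DCAF12 (0.34, adjusted p = 0.55) and DptB (0.85, adjusted p = 0.772). Immune effectors had 1 of 9 rhythmic members over all and 6 adjusted over the list alone. The count was 0 with a linear slope in hours, and 2 without CT22 and without the ZT2, ZT18 and CT2 arrays.

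The rhythms of LD and DD differed for 1 probe set, that of CG2121, by an amplitude of 0.88 ± 0.09 (SE, adjusted p = 0.00481). Its fitted amplitude was 0.82 in LD and 0.21 in DD. For the other genes nearest the threshold, MME1 (0.56, adjusted p = 0.126), t (0.69, adjusted p = 0.193), Usp8 (0.72, adjusted p = 0.193) and CG9837 (0.57, adjusted p = 0.326), the difference did not pass. An unadjusted p under 0.05 was found for 468 probe sets, again fewer than the 698 that chance gives. Phototransduction had 0 members over all and 4 adjusted over the list alone, rdgC (0.50), Gbeta76C (0.41), trpl (0.39) and inaD (0.32). The call of CG2121 was lost without ZT10 or CT22, which left 0 probe sets. Leaving out ZT2, ZT18 and CT2 left 1.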

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

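The tests of the body transcripts, those without the ZT2, ZT18 and CT2 arrays, that of the fat body list, that on day arrays left out of the choice of probe sets, those of RNA quality and those with an estimated correlation in other fits were chosen only after the result was seen. The regroupings of the arrays, the slope in hours, the change between the nights and the spread of the day arrays were fixed before their results, though after the levels of the lists on each array had been seen.

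The level of each of the 30 lists was examined on the 6 arrays of each day, and in 6 of 60 cases 1 array stood apart, where chance gives 3. For gut enzymes this was ZT2 in LD, with a gap to the nearest array of 0.73 of the whole range, and CT2 in DD, with 0.76. For the male reproductive tract it was CT2 in DD (0.69). Proteasome genes stood apart at CT14 (0.71), as did neuron markers at CT14 (0.71), and ecdysone and juvenile hormone genes at CT18 (0.66).

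The high gut and male reproductive tract transcripts at ZT2, ZT18 and CT2 may come from RNA of other body parts, since heads were collected on sieves from broken frozen flies, and the lists share no gene with each other or with the rest. The gut list lay above the other 9 arrays on 3 of 3, as did 9 of 22 gut genes and 12 of 17 male genes (at ZT2 betaTry reached 8.66 and Mst57Da 7.26), but the 3 arrays were picked by the levels of these same lists, so this describes the pattern and is no independent test of it. Carry-over of ovary tissue is argued against by the eggshell list, above the others on 0 of the 3 arrays, but other tissue of females was not tested by it. The spike-in BioB was above the others on 2 of the 3 (8.77 and 8.78) but below them at ZT2 (7.87). Its values were read after RMA, so they cannot decide whether an array was brighter or dimmer. A time-of-day effect at hour 18 present on both days is argued against by the male list at CT18, at -0.18. An effect at hour 18 limited to the LD day cannot be told apart from carry-over. At hour 2 a time-of-day effect cannot be told apart from carry-over either, because the hour 2 array was the highest on both of the 2 days and each hour was sampled on 1 array per day. How far heads themselves express these genes was not examined.

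The list of antimicrobial genes had a day minus night mean of 0.29 in LD, where 6 of 9 were positive, 0 rose and Def fell by 0.62, and of 0.55 in DD, where 8 of 9 were positive and 3 rose (adjusted p = 0.438 and 0.356 with an estimated correlation). The days disagreed at hour 2: the list level was -0.17 at ZT2, within the range of the LD night arrays (-0.19 to -0.06), and 0.49 at CT2, the highest of all arrays. The LD mean is therefore larger in fits that leave out ZT2. Carry-over of body RNA as the whole cause is argued against by the sizes in DD without the 3 arrays, Drs at 1.09 (adjusted p = 0.00195), DptB at 0.97 (adjusted p = 0.000162) and Mtk at 1.41 (adjusted p = 8.87e-05; over all alternatives up to 0.39, 0.483 and 0.547), which are the same without CT2 alone, the 1 of the 3 arrays in this contrast, where the calls were lost (adjusted p = 0.053, 0.053 and 0.192), by the calls kept with the covariate of body transcripts (adjusted p = 0.000956, 0.00599 and 0.0016), and by list means of 0.42 in LD and 0.44 in DD (adjusted p = 0.201 and 0.092 with an estimated correlation, 6e-07 and 4.73e-10 with the preset one), and a general rise of fat body transcripts by the fat body list, at -0.20 in DD. Against a steady drift shared by both days stands the mean of 0.55 in DD with a slope in hours (adjusted p = 0.000227 with the preset correlation, 0.634 with an estimated one, and 0.125 and 0.754 in LD). The calls of single genes ended as their SE grew, for Drs from 1.16 ± 0.16 to 1.00 ± 0.26 and for Mtk from 1.67 ± 0.28 to 1.80 ± 0.46. From hour 2 to hour 10 the list level rose in LD (-0.17, 0.30, 0.34) and fell in DD (0.49, 0.24, 0.07). A single slope for both days averages over these opposite courses, so it could not show a drift within DD. A drift that differed between the days was not tested. In exact permutation tests of the list level the difference gave p = 0.3 in LD and p = 0.1 in DD, the smallest that 10 splits allow, and p = 0.015 for the sum of both over 400 pairs of splits, all 2-sided. No prediction had been written for these tests. The list was taken up for its shift on these same arrays, and the p are not adjusted for that choice among 30 lists. A daily change of immune gene expression that does not need timeless may remain as an untested hypothesis, which several samples per hour with wild-type flies beside them would test; handling or feeding at fixed hours was not recorded in the labels and stays open.

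Between LD light phase and DD subjective day 26 probe sets were called, and between the nights 0 (680 with an unadjusted p under 0.05 with limma). Body RNA as the whole cause is argued against by the 26 probe sets that kept their call with the covariate of body transcripts and the 14 that did without the 3 arrays (20 without ZT2 alone, but 4 without CT2 alone). The median SD was 0.0999 for the day arrays and 0.0969 for the night arrays. Both contrasts use 1 variance per probe set shared by all 12 arrays, so these SDs decide nothing about the difference in calls. A difference between the days that does not depend on light stays open: 22 of the 26 went the same way between the nights, with a median of 0.13 (0.06 to 0.15 over the 3 night hours), and the bound of 0.27 set from the median of 0.55 by day was wrong, because the 26 were chosen for their size by day. Probe sets called without the day arrays of hour 2 or hour 6 had medians of 0.27 and 0.31 on those arrays and of 0.10 (0.07 to 0.21) and 0.13 (0.08 to 0.22) over the 3 night hours. The highest night hour was thus too close to exclude it, and without those of hour 10 there were 2. RNA quality may be part of such a difference, as the 3' minus 5' signal of eIF-4a was higher in LD by 0.38 by day and by 0.32 by night. With it as a covariate the 26 calls ended while their median size went from 0.55 to 0.58 and the SE from 0.10 to 0.14, so a contribution of RNA quality to their size was not shown. An effect of light on these transcripts was not shown, as the direct test of the difference called 0 probe sets, and 4 with that covariate, 3 with array weights, 3 with the covariate of body transcripts, 2 with robust moderation or without ZT2, and 1 with a slope in hours or without ZT14 or CT6. The direct test was not run with clock hour as a block, so what pairing the arrays by hour would give is not known.

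The test of a difference between LD and DD singled out 5 results. The rhythm of CG2121 differed by an amplitude of 0.88. The day-night contrast differed by 0.20 for lipid metabolism, 0.13 for activity-regulated genes, 0.12 for glycolysis and -0.26 for immune effectors, and none of these 4 lists passed with an estimated correlation.

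Regroupings of the same arrays were counted beside each result. For contrasts of 3 arrays against 3 there are 10 splits, too few for a share under 0.05: light against dark phase in LD gave 18 probe sets and 12 lists, with at most 5 and 8 in another split. For DD subjective day against night the values were 9 and 7, with at most 2 and 6. They were for LD light phase against DD subjective day 26 and 3, with at most 6 and 8, and for the nights 0 and 0, with at most 1 and 4. For LD light phase against DD subjective day, 8 of the 10 splits, the real one included, gave at least as many lists as the 3. For the LD rhythm, 1 of 60 orders of the hours, the real one, gave as many as the 15 probe sets, a share under 0.05. Another order gave 14, so chance was not firmly excluded. For the DD day against the LD day, 3 of 100 regroupings, the real one included, gave as many as 3, also a share under 0.05. That count was 0 without any of 6 single arrays, and another regrouping called many more. Chance was therefore not firmly excluded here either. The regrouping that exchanged ZT22 and CT14 called 75, which points to a structure of the samples other than the day. On the second principal component (17.6% of the variance) CT6 (3.0) and CT14 (2.2) lay among the LD arrays (-0.6 to 11.7) and the other 4 DD arrays at -11.5 to -3.1, and the cause of this was not tested. Chance was not excluded for the DD rhythm (17 of 60 orders gave as many as 1, highest other 10). The same holds for the difference of the rhythms (6 of 32 swaps gave as many as 1, highest other 7) or the difference of the day-night contrasts (100 of 100 gave as many as 0, highest other 4). For lists it was not excluded in the difference of the contrasts (45 of 100 gave as many as 4, highest other 8) or between the days (90 of 100 gave as many as 1, highest other 9).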

How the results depend on the processing

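The fits without the ZT2, ZT18 and CT2 arrays and with the covariates of body transcripts and of RNA quality were chosen after the result was seen. Where not stated, the cause of a moved value was not tested.

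Most counts moved by over 1.5 times under some alternative. With probe sets above the median signal, which tests fewer probe sets, LD light phase against DD subjective day gave 42 and the comparison of days 20. Quantile normalization gave 15 and 18 for these, median centring 13 for the first and 8 for light against dark phase in LD, and no intensity trend 15 for the first. Robust moderation gave 4 for subjective day against night in DD, 2 for the difference of the contrasts, 59 for LD light phase against DD subjective day, 19 for the days. For the LD rhythm it gave 24 and for the difference of the rhythms 2. Array weights gave 28 for light against dark phase, 3 for the difference of the contrasts, 65 for LD light phase against DD subjective day, 31 for the days and 38 for the LD rhythm.

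A linear slope in hours gave 0 for both day-night contrasts, 1 for their difference, 65 for LD light phase against DD subjective day, 49 for the days, 68 for the LD rhythm, 0 for the DD rhythm and 2 for the difference of the rhythms. Within a day hour and phase nearly coincide, which leaves the day-night contrasts little information. The compared arrays alone, with fewer degrees of freedom, gave 1 for light against dark phase, 18 for subjective day against night, 0 for LD light phase against DD subjective day and 6 for the LD rhythm. Clock hour as a block gave 142 for LD light phase against DD subjective day and 118 for the days. It was not run for the day-night contrasts, their difference or the rhythms. With the ZT2, ZT18 and CT2 arrays left out light against dark phase gave 31, the days 26, the LD rhythm 7 and the DD rhythm 2, and the covariate gave 47, 18, 3, 97, 1 and 35 for the 6 contrasts in the order of the methods, 33 for the LD rhythm and 3 for the difference of the rhythms. The 3' minus 5' signal of the eIF-4a control as a covariate gave 3, 16, 4, 1, 0 and 0 for the 6 contrasts and 2 for the difference of the rhythms; it nearly follows the day, so SEs between the days grew.

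Leaving out 1 array gave 2 (ZT6) to 54 (ZT2) for light against dark phase, with 3 without ZT10, ZT22 or CT22, 4 without ZT18 or CT18, 8 without ZT14, 9 without CT6 and 11 without CT14. It gave 0 (CT2, CT22) to 18 (ZT2) for subjective day against night, with 1 without CT18 and 4 without CT14. The range was 0 to 2 (ZT2) for their difference, with 1 without ZT14 or CT6. For LD light phase against DD subjective day it gave 1 (ZT6, CT10) to 168 (CT6), with 4 without CT2, 7 without CT22, 11 without CT18, 16 without ZT22, 17 without ZT18 and 56 without ZT2. For the nights it gave 0 to 0, and for the days 0 (ZT6, ZT14, ZT18, CT10, CT18, CT22) to 95 (CT6), with 7 without ZT10, 25 without ZT22, 31 without CT14 and 46 without ZT2. For the LD rhythm it gave 1 (ZT10) to 22 (ZT14), with 9 without CT18, for the DD rhythm 1 to 2 (CT22), and for the difference of the rhythms 0 (ZT10, CT22) to 2 (ZT14).

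Among lists, 0 passed with an estimated correlation in the 5 contrasts that had calls, and with all probe sets of each gene 0 passed between the days. Without the 3 arrays 6 lists passed for LD light phase against DD subjective day, 1 between the nights and 2 between the days, and with the eIF-4a covariate 5, 8 and 6. Without 1 array the lists that passed numbered 6 to 12 for light against dark phase (6 without ZT14, 7 without ZT2), 3 to 9 for subjective day against night (3 without CT2 or CT10, 4 without CT14), 2 to 7 for their difference (7 without CT18; 2 without ZT14, ZT18, CT2, CT6, CT10, CT14 or CT22). They numbered 3 to 7 for LD light phase against DD subjective day (7 without CT2, 6 without ZT2, 5 without ZT10), 0 to 3 for the nights (3 without ZT2 or ZT22, 2 without ZT14) and 0 to 3 for the days (0 without CT18). The direction reversed for gut enzymes between light and dark phase, to -0.01 without the 3 arrays and -0.08 without ZT2, and for the male reproductive tract, to -0.13 without ZT2. Leaving out ZT6 raised them to 0.40 and 0.34, and the high level of both lists on ZT2 accounts for these moves.

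Of the named genes, CG2121 kept its LD rhythm in 23 of 23 alternatives, with adjusted p from 1.05e-05 to 0.0182, CG5455 its call between LD light phase and DD subjective day in 22 of 24 and Drs its DD rhythm in 22 of 23. Usp8, Lsd-1 and Def kept their LD light-dark calls in 9 of 23 and rdhB in 7 of 23. Over all named genes 165 values lost their call in the alternatives and 304 with 1 array left out, and 0 reversed. The files give no background levels, so which dim probe sets were above background was not examined.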

Other observations

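The correlation test below was fixed before its result was seen; the lists below are the rest of those fixed in advance.

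In the LD day-night contrast the other 18 lists did not pass with camera (adjusted p from 0.0926 to 0.994). Their mean changes, light minus dark, were 0.05 for 13 core clock genes, 0.04 for 10 reported clock outputs, -0.03 for 11 genes of histamine, dopamine and serotonin handling, 0.07 for glycolysis and -0.06 for starvation and insulin signalling. Detoxification genes were near 0, at 0.01 for 83 cytochrome P450 genes, 0.03 for 34 glutathione S-transferases and 0.00 for 33 UDP-glycosyltransferases, as were 7 antioxidant genes (0.01). Ribosomal proteins were at -0.03, proteasome genes at 0.01, neuropeptides at 0.00 and genes of ecdysone and juvenile hormone at 0.02, with a median of -0.06. Markers of neurons were at -0.07, glia 0.06, muscle 0.01, eggshell -0.05 and hemocytes 0.01.

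Single members of these lists passed adjusted over the list alone and not over all probe sets. In LD these were MsrA of the ecdysone and juvenile hormone list, higher in the light by 0.50, and, of the reported clock outputs, trpl (0.66) and Pdh (-0.31). In DD the neuropeptide gene Mip was higher in the subjective day (0.40) and CCHa2 lower (-0.38), and the cytochrome P450 gene Cyp18a1 was at -0.34 within the list of reported clock outputs. Between the days, DD minus LD, markers of several kinds passed: the glial transcription factor gene repo (-0.29), the neuronal genes nSyb (0.21) and Gad1 (0.16) and the muscle genes Mlc2 (0.20) and up (0.24). The glycolysis genes Pgi and Gpdh1 were at -0.28 and -0.23, and trpl, among the reported clock outputs, at -0.33. The mitochondrial superoxide dismutase gene Sod2 was at 0.23, and t was at 0.74.

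If time of day acted alike with and without light, the day-night changes of LD and DD could correlate across genes beyond what regrouped arrays give. Across 10844 genes, which are not independent replicates, the correlation was 0.22 (Spearman 0.08), and 20 of 100 pairs of splits gave one as large, up to 0.36. With the ZT2, ZT18 and CT2 arrays left out it was 0.18 (Spearman 0.11), and 6 of 60 pairs gave one as large, up to 0.24. The test therefore gave no evidence of a shared effect across genes beyond chance regroupings. It does not speak about single genes. CG4757 (0.86 in LD and 1.01 in DD) and retinin (-0.72 and -0.62) passed over all probe sets on both days, each in the same direction.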
